A study of Mus musculus with 2 samples.

How the data were processed

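H3K9me3 ChIP-seq had been carried out on midbrain of B6NCrl mouse embryos at embryonic day 10.5, in 2 biological replicates that the labels describe as pools of 69 and 51 embryos, males and females together. Both replicates form 1 group, so no comparison between groups was possible. The labels give the replicates as separate biological samples, and p-values do not measure the spread between them: they compare the positions of peaks with rotated positions.

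The deposited files used were 4 peak lists in narrowPeak format. Per the deposited README texts, the replicate lists were each called on that replicate's alignments against its own control, the pooled list on the alignments of both replicates with both controls, and all coordinates are on assembly mm10. The replicated list is named as such by the authors, and the rule for keeping a peak was not given in the sources used here; each of its 53254 peaks on all sequences was found with identical values in the deposited pooled list. The aligner, the peak caller, read filters and read depth were not given in the sources used here. The score column of the deposited lists, a display score per peak, was not analysed. The signal value, the authors' enrichment value per peak on a scale they do not state, was used to rank peaks within a list. The authors gave a −log10 p and a −log10 q of each peak, per the deposited narrowPeak format, and the latter set a stricter threshold; the smallest deposited −log10 p in any list was 2.00. Lists of different lengths came with different medians of the signal value (3.49 in replicate 1, 3.54 in replicate 2), which were not compared as levels. The README texts hold no measurements and were not used as data.

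The reference was GRCm38, the same build as mm10, with the GENCODE M21 annotation. Peaks on chromosomes 1 to 19, X and Y were analysed. Peaks on the mitochondrial genome and on unplaced or unlocalized sequences (567 in replicate 1, 510 in replicate 2 and 402 in the replicated list) were left out of every comparison because they hold few annotated genes and cannot be rotated sensibly, and they are described separately. No list of excluded regions was applied. Coordinates are 1-based.

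The background was made by rotation: all peaks of a chromosome were shifted together by a random offset, wrapping at the chromosome end, 1000 times per test (100 times for base composition, seed 60719). This keeps the widths, numbers and local clustering of peaks. Two-sided permutation p-values from 1000 rotations cannot fall below 0.002, one-sided ones below 0.001 and those from 100 rotations below 0.0198. Benjamini-Hochberg adjustment was made over the 23 gene lists and, separately, over the 4 classes of genomic feature, with a threshold of 0.05. Overlap between replicates needed at least 1 bp. A gene carried a peak when at least 1 bp of a replicated peak lay from 2 kb upstream of its start to its end; imprinted genes, of any gene type, were read within 5 kb of the start. Promoters reached 1 kb to each side of a transcript start of protein-coding genes. Peaks went to promoter, exon, intron or intergenic sequence by their midpoint. Exons and introns were those of protein-coding genes only, so genes of other types count as intergenic. Zinc finger clusters were genes with at least 4 other zinc finger genes starting within 500 kb. First and last exons were those of the longest transcript of genes with at least 2 exons. Peaks within 10 kb were joined to domains. Intervals for shares are 95% Clopper-Pearson intervals and cover counting error only.

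The gene lists, the tests, the rule for named genes and most alternative settings were fixed before the data were examined. Lists of gene families were taken by name pattern from the 21911 protein-coding genes, and the other lists by symbol. All symbols matched the annotation except Zscan4a and Dux, which left 23 of 25 early cleavage genes. The number of genes in more than 1 list was 7 (Krt5, Krt8, Krt14, Krt18, Rpl10l, Zfp352 and Zfp57). Named genes were each imprinted gene with a replicated peak within 5 kb of its start, the 4 members of every other list with most covered bases, the 10 protein-coding genes outside the lists with most covered bases at 1 per domain, the 5 strongest replicated peaks, and the 10 broadest domains by covered bases. Members of the midbrain, neuron and other cell type lists without a peak are given as counts. Usp29, Blcap and Kcnq1 are named only as neighbours of imprinted genes.

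The tests were first tried on simulated data made by rotating the replicated peaks. Over 100 rotated peak lists, each tested with 200 rotations over the gene lists, a mean of 2.87% of list tests fell below a p of 0.05, and the highest share of any list was 10%. Peaks planted on 30% of the members of a list, in 20 runs, led to a call in 98.3% of runs for the 6 lists of at least 80 members and in 54.4% for smaller lists. On 50 rotated lists 2% of tests of replicate overlap fell below 0.05. With no association, the share below 0.05 was 2% for clustered zinc finger genes, 3% for zinc finger exons and 4.75% for genomic features.

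Alternative settings fixed in this way were peaks with −log10 q of at least 2, the 50% of each list with the higher signal values (more where values were tied), each replicate's own list alone, the pooled list, other windows around genes, an overlap of at least 200 bp or of 50% of the peaks, peaks within 1 kb merged first, equal numbers of peaks, a promoter of 2 kb, assignment by any overlap, other definitions of clusters, merge distances of 5 and 25 kb, and 10000 draws of random genes matched on length in 50 classes. Replicated peaks that overlap both replicates (35662), rotation without runs of N, and the whole window of imprinted genes were added after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.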

Results

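Trimethylation of histone H3 at lysine 9 (H3K9me3), a mark of heterochromatin and of silenced repeats and gene clusters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the midbrain of mouse embryos of strain B6NCrl at embryonic day 10.5. The midbrain at this age consists largely of dividing neural progenitors and the first neurons. The series held 1 group with 2 biological replicates, pools of 69 and 51 embryos of both sexes. There was no second tissue, age or treatment, so the comparisons were between the replicates and between the peaks and the annotated genome (build mm10, GENCODE release M21). With 2 replicates no SD is printed, and the counts for the 23 gene lists are given also for each replicate's own peaks. Peaks had been called by the authors on each replicate, on the pooled replicates, and as a shorter list of replicated peaks. The number of sequenced reads behind each list was not given in the sources used here, so the depth is unknown. Each peak's signal value is the authors' own and was used only within a list.

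On chromosomes 1 to 19, X and Y, the replicate 1 list held 139905 peaks over 44.7 Mb, or 1.64% of the chromosome sequence, with a median width of 220 bp. The replicate 2 list held 64033 peaks over 14.3 Mb, or 0.524%, with a median width of 168 bp. Replicate 1 thus had 2.18 times as many peaks and 3.13 times as many covered bases. The pooled list held 184241 peaks over 48.9 Mb. The replicated list, on which the comparisons with genes rest, held 52852 peaks over 26.6 Mb, or 0.977%, with a median width of 378 bp and a widest peak of 15337 bp.

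The strongest replicated peak, with a signal value of 18.1, covered chromosome 12 from 80754121 to 80759492, in an exon of Ccdc177, a coiled-coil protein gene. Of the same list, the peak with a signal value of 17.5 lay on chromosome 18 at 37752085 to 37759238, over exons of the protocadherin genes Pcdhgb7 and Pcdhga11. A peak of 17.3 covered the exon of Klf14, a Krüppel-like transcription factor gene, on chromosome 6 at 30956207 to 30959038. The other two of the strongest 5 lay in exons of Trim71, which encodes an RNA-binding protein of early development (15.9; chromosome 9, 114510674 to 114514409), and of the zinc finger gene Zfp873 (15.8; chromosome 10, 82058245 to 82061773). All 5 overlapped a peak in each replicate.

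Peaks in the highest signal decile of either replicate were shared more often than those in the lowest. Of the replicate 1 peaks, 36365 (26.0%) overlapped a replicate 2 peak by at least 1 bp, and 44177 replicate 2 peaks (69.0%) overlapped a replicate 1 peak. The shares depended on the rule: they were 8.99% and 19.6% when at least 50% of both peaks had to overlap, and 42.3% and 55.6% with equal numbers of the strongest peaks. When the replicate 2 peaks of each chromosome were shifted together by a random offset, 1.48% and 3.37% overlapped on average, and at most 3.72% and 8.96%. The Jaccard index of covered bases was 0.198, against 0.00533 on average and 0.0168 at most after rotation. For the 3 measures the one-sided permutation (rotation) p was 0.001, the smallest that 1000 rotations can give. In the decile of replicate 1 peaks with the highest signal values 77.8% were shared (95% Clopper-Pearson interval 77.1 to 78.4), against 10.5% in the lowest decile. For replicate 2 these shares were 95.6% (95.03 to 96.06) and 58.6%, as the plot of shared peaks by signal decile shows. These intervals cover counting error only, since neighbouring peaks are not independent. No rotated share was taken by decile, and wider peaks meet a 1 bp rule more easily. In the pooled list the median width was 140 bp in the lowest signal decile and 527 bp in the highest, so signal and width were not separated. Across 46275 overlapping pairs of peaks, the signal values of the replicates were related with a Spearman rho of 0.273 (95% interval 0.264 to 0.281), across peaks of a pair of libraries that are not independent observations. With pairs limited to those that covered at least 50% of both peaks, rho was 0.405.

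**Figure D1:**
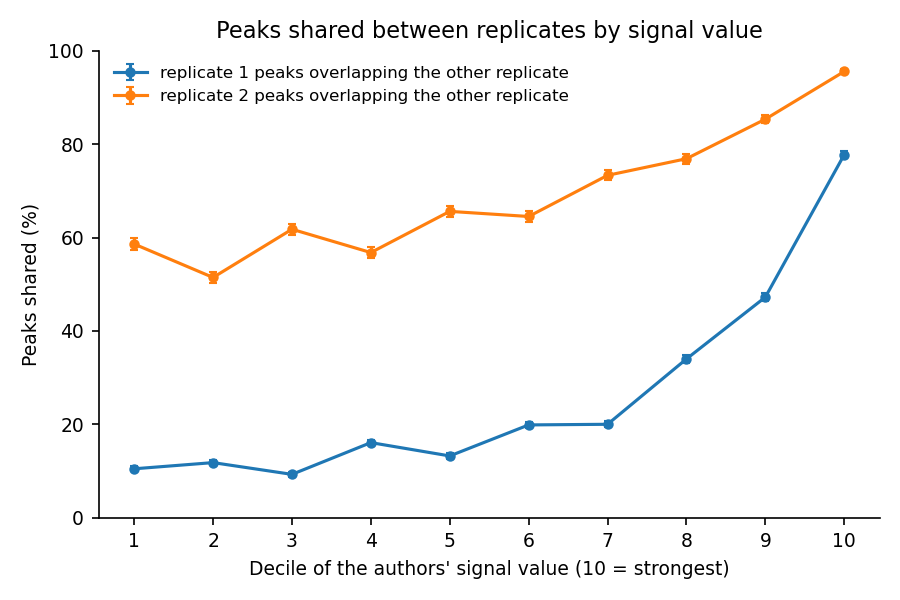
Percent of each replicate's peaks that overlap a peak of the other replicate by at least 1 bp (y axis), by decile of the authors' signal value within that replicate's list (x axis, 10 is the strongest); bars are 95% Clopper-Pearson intervals. The share reaches 77.8% in replicate 1 and 95.6% in replicate 2 in the strongest decile.

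Of the replicated peaks, 35662 (67.5%) overlapped a peak in each replicate, 14999 (28.4%) a replicate 1 peak alone, 1770 (3.35%) a replicate 2 peak alone, and 421 (0.797%) a peak of neither replicate. The replicated list is therefore not a list of peaks called in both replicates, and the counts from each replicate's own peaks stand beside those of each gene list.

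Among the 23 gene lists, each read in its own window, the clustered protocadherin genes had the highest share of members with a peak. Imprinted genes, read within 5 kb of the start, would reach 28 of 28 if read from 2 kb upstream to the gene end. The protocadherin genes encode neuronal adhesion proteins in alpha, beta and gamma arrays on chromosome 18. A replicated peak lay between 2 kb upstream and the gene end in 52 of 56 members (92.9%), against 37.1% on average after rotation of the peaks, and in 56 members in replicate 1 and 55 in replicate 2. In Pcdhga1 (37661793 to 37841873) 103924 bp were covered by 54 peaks, and in Pcdhga2, Pcdhga3 and Pcdhgb1 99387, 95376 and 89774 bp were covered. These gene windows nest in each other because the gamma genes share their last exons, so the 4 values count largely the same bases. The map of the region shows blocks of peaks over much of the 3 arrays in both replicates. The members without a replicated peak were Pcdhac2, the last gene of the alpha array, and Pcdhgc3, Pcdhgc4 and Pcdhgc5, the last of the gamma array. Peaks also lay upstream of the first alpha gene, Pcdha1 (start at 36930184). In the bin from 36900001 to 36905000 they covered 85.7% in replicate 1 and 66.8% in replicate 2.

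**Figure D2:**
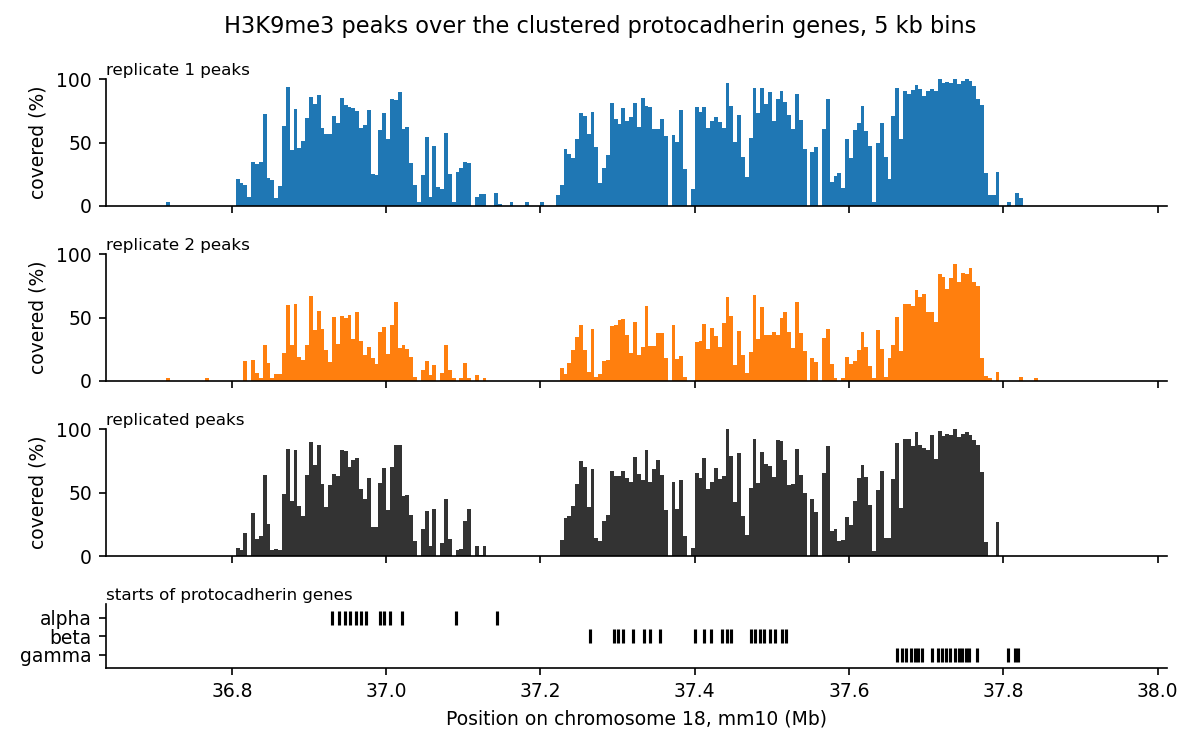
Percent of each 5 kb bin covered by peaks (y axes) along chromosome 18 in mm10 (x axis, Mb), for replicate 1, replicate 2 and the replicated list, with the starts of the protocadherin alpha, beta and gamma genes as ticks. A replicated peak overlapped 52 of the 56 gene windows.

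Zinc finger genes, many of which encode KRAB-type repressors of transposable elements, carried peaks in 225 of 391 members (57.5%, against 23.4% after rotation), with 289 in replicate 1 and 226 in replicate 2. The members with most covered bases were Zfp943 on chromosome 17 (21962552 to 22071168; 34915 bp in 52 peaks), Zfp936 on chromosome 7 (43114229 to 43192109; 33374 bp), Zfp981 on chromosome 4 (146502027 to 146539395; 22770 bp) and Zfp951 on chromosome 5 (104813169 to 104860070; 19424 bp). Vomeronasal receptor genes, which encode pheromone receptors, carried peaks in 136 of 326 members (41.7%, against 19.2%), with 167 in replicate 1 and 138 in replicate 2. Vmn2r60 on chromosome 7 (42107770 to 42196208) was covered over 30250 bp, its neighbours Vmn2r59 and Vmn2r61 over 16743 and 16238 bp, and Vmn2r53 over 16163 bp. Cytochrome P450 genes, which encode oxidative enzymes of drug and steroid metabolism, carried peaks in 41 of 94 members (43.6%, against 23.1%), with 55 in replicate 1 and 40 in replicate 2. Covered most were the drug-metabolising Cyp3a57 (22293 bp), Cyp3a11 (16967 bp) and Cyp3a16 (14941 bp) on chromosome 5 and Cyp2c38 (16080 bp) on chromosome 19.

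Germ cell genes, which act in meiosis and the piRNA pathway and are silent in somatic tissue, carried peaks in 20 of 28 members (71.4%, against 27.2%), with 24 in replicate 1 and 21 in replicate 2. Dazl, an RNA-binding regulator of germ cell development on chromosome 17 (50279395 to 50293636), was covered over 2085 bp by 2 peaks, the stronger with a signal value of 9.60. Taf7l, a germ cell transcription factor subunit on the X (134460118 to 134476490), was covered over 1533 bp, and the piRNA pathway genes Mael and Tdrd1 over 1384 and 1382 bp.

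Genes at germline imprinted regions, where 1 parental allele is methylated, were read at the promoter. A replicated peak lay within 5 kb of the start of 19 of 28 (67.9%, against 11.7% after rotation), with 24 in replicate 1 and 21 in replicate 2. The strongest lay upstream of the maternally expressed RNA gene Meg3 (chromosome 12, 109536985 to 109540370; signal value 11.1) and over the first exons of Peg3 and Usp29 (chromosome 7, 6728187 to 6731202; 10.2). Others covered the starts of Nespas (9.50) and Gnas (8.23), which share 1 complex locus on chromosome 2, of Nnat (9.07), a small neuronal membrane protein gene inside Blcap, and of Airn (8.83), the antisense RNA of Igf2r (3.85). A peak of 7.75 on chromosome 6 (4746454 to 4748815) covered the shared start of Sgce and Peg10. Signal values at Zrsr1, Peg13, Snurf and Nap1l5 were 7.77, 7.31, 7.24 and 6.72. Kcnq1ot1, the antisense RNA of the Kcnq1 region, had a peak of 5.29, and H19, an untranslated growth-regulating RNA, had a peak of 5.22 centred at -2959 bp from its start (chromosome 7, 142579987 to 142582216). The remaining members with a peak were Mcts2 (4.91), Slc38a4 (4.68), Fkbp6 (3.92) and Gpr1 (3.62). The other 9 had none within 5 kb of the annotated start.

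By the two-sided permutation (rotation) test, with Benjamini-Hochberg adjustment over the 23 lists, the adjusted p was 0.00919 for the protocadherin, zinc finger, vomeronasal, germ cell and imprinted lists, each at the smallest unadjusted p that 1000 rotations can give (0.002), and 0.0153 for the cytochrome P450 list. The zinc finger call ended when peaks were sought only within 2 kb of the gene start (52 genes, adjusted p 0.230 by the permutation test, range over 11 alternatives 0.000657 to 0.230). The vomeronasal call ended with replicate 1 peaks alone (167 genes, adjusted permutation p 0.0766) and pooled peaks (177, adjusted permutation p 0.230, range over 11 alternatives 0.000657 to 0.230). The cytochrome P450 call held in 6 of 11 alternatives (adjusted permutation p 0.000657 to 0.368), and it ended with either replicate alone.

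**Figure D3:**
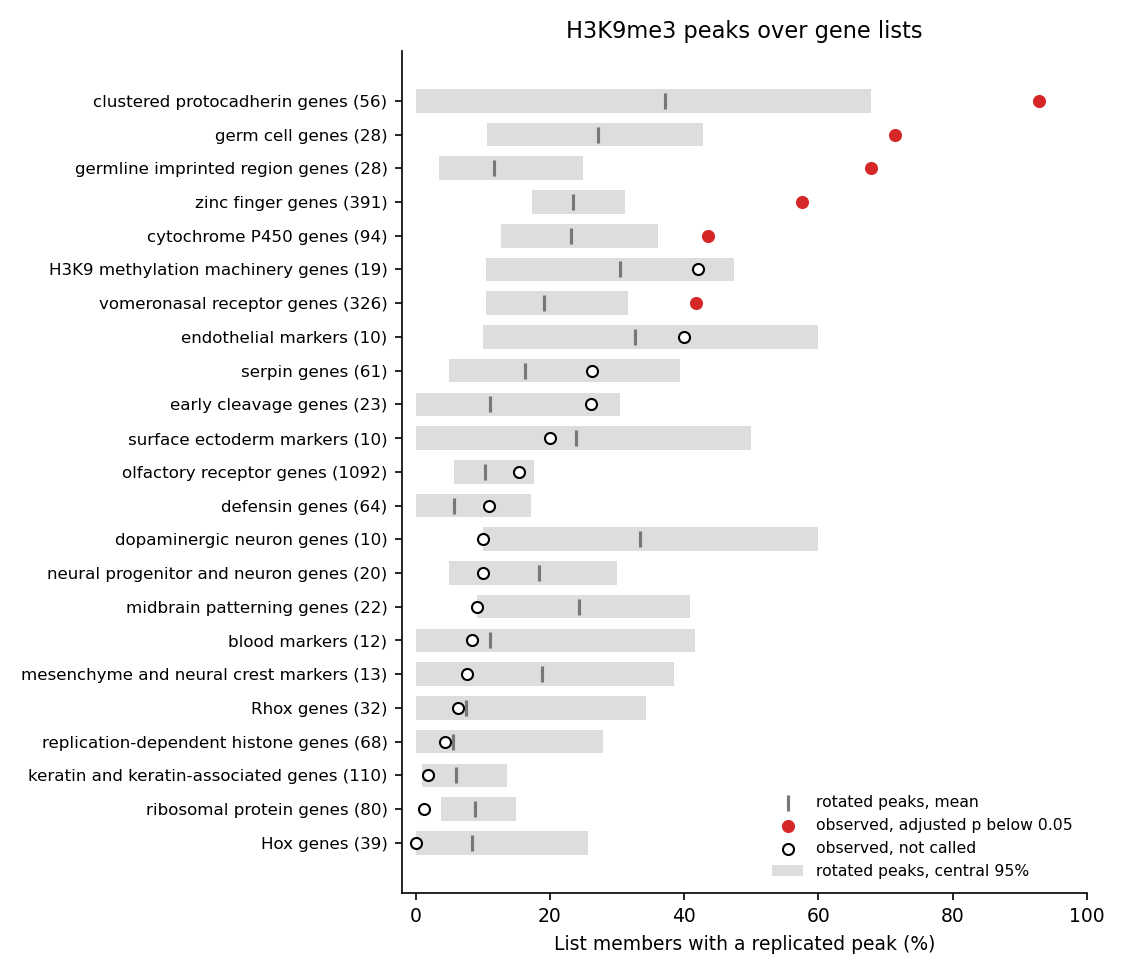
Percent of the members of each gene list with a replicated peak (x axis; points), with the mean (tick) and central 95% range (grey bar) over 1000 rotations of the peaks and the number of members in brackets. The 6 lists with an adjusted p below 0.05 are filled; protocadherin genes stand highest at 92.9%.

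The other 17 lists were not called. Of 1092 olfactory receptor genes, which encode odorant receptors, 169 (15.5%, against 10.4% after rotation) carried a peak, with 312 in replicate 1 and 202 in replicate 2 (adjusted permutation p 0.358). Olfr398, Olfr139 and Olfr403 on chromosome 11 and Olfr1349 on chromosome 7 were covered over 8764, 8474, 6079 and 6701 bp. With random genes of matched length in place of rotated peaks, the olfactory list passed (adjusted permutation p 0.000657, range over 11 alternatives 0.000657 to 0.402). Serpin genes, which encode protease inhibitors, carried peaks in 16 of 61, led by Serpinb6d (7628 bp), Serpina1b, Serpina1e and Serpinb9e, with 34 in replicate 1 and 16 in replicate 2 (adjusted permutation p 0.382). Defensin genes, which encode antimicrobial peptides, carried peaks in 7 of 64, led by Defb33 (5515 bp), Defb39, Defb7 and Defb8, with 21 in replicate 1 and 7 in replicate 2 (adjusted permutation p 0.420). Early cleavage genes, active in the early embryo, carried peaks in 6 of 23, with Pramef12 (3012 bp), Pramef6, Pramef25 and Pramef17 covered most, and with 9 in replicate 1 and 6 in replicate 2 (adjusted permutation p 0.358). Of the genes for the methylation of H3K9 itself 8 of 19 carried a peak, with 11 in replicate 1 and 7 in replicate 2 (adjusted permutation p 0.480), among them Atf7ip, a partner of the methyltransferase Setdb1 (9644 bp), the chromatin remodeller Atrx (1475 bp), and the methyltransferases Suv39h1 (883 bp) and Setdb1 (376 bp).

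Genes of the tissue's own identity were not called, and the replicates' own lists held peaks in more of them than the replicated list. Of the midbrain patterning genes 2 of 22 (9.09%, against 24.4% after rotation of the replicated peaks) had a replicated peak (adjusted permutation p 0.276). These were the roof and floor plate factor Lmx1a (527 bp) and the dorsal factor Pax7 (402 bp). In replicate 1 6 had a peak, in replicate 2 8 (adjusted permutation p 0.986 with these peaks alone) and in the pooled list 10. The low share was thus not seen with replicate 2 or pooled peaks. Of the neural progenitor and neuron genes 2 of 20 had one, Sox3 (1000 bp), a progenitor factor, and Dll1 (372 bp), a Notch ligand, with 5 in replicate 1 and 4 in replicate 2 (rotated mean for replicated peaks 18.4%; adjusted permutation p 0.616). Of the dopaminergic neuron genes 1 of 10 had one, Ddc (542 bp), which encodes a decarboxylase of dopamine synthesis, while 4 had one in replicate 1 and 4 in replicate 2 (rotated mean for replicated peaks 33.5%; adjusted permutation p 0.359). Markers of other cell types carried peaks in 1 of 12 blood genes (Gata1, an erythroid factor, 2098 bp), 4 of 10 endothelial genes (Pecam1, Flt1, Tek and Sox17), 1 of 13 mesenchyme and neural crest genes (Col1a1) and 2 of 10 surface ectoderm genes (Grhl2 and Cdh1), with adjusted permutation p of 0.618 for the mesenchyme and neural crest list and 1 for the other 3. In replicate 1 and replicate 2 the counts were 2 and 1 for blood, 7 and 3 for endothelial, 4 and 3 for mesenchyme and neural crest, and 3 and 2 for surface ectoderm genes.

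Hox genes, the body axis patterning factors, had a replicated peak in 0 of 39 members (rotated mean 8.42%; adjusted permutation p 0.382), with 3 in replicate 1 and 4 in replicate 2. Ribosomal protein genes, active in nearly all cells, had 1 of 80 (1.25%, against 8.88%), which was Rpl10l, a germ cell paralog that also belongs to the germ cell list; replicate 1 had 6 and replicate 2 had 5. Keratin and keratin-associated genes had 2 of 110 (Krtap4-16 and Krtap9-5), replication-dependent histone genes 3 of 68 (Hist1h2aa and Hist1h2ba under 1 shared peak, and Hist1h2be), and the X-linked reproductive homeobox genes of the Rhox cluster 2 of 32 (Rhox13 and Rhox10). Their adjusted permutation p was 0.420 for the keratin list and 1 for the histone and Rhox lists. In replicate 1 and replicate 2 the counts were 11 and 3 for keratin, 3 and 2 for histone, and 7 and 2 for Rhox genes. No list was called depleted: 0 of the 23 passed the two-sided permutation (rotation) test on that side. The ribosomal list was the 1 with an unadjusted p below 0.05 there (permutation p 0.0200, adjusted 0.0656). For the Hox, histone, defensin, Rhox and early cleavage lists the lower end of the central rotated range was already 0. The same held for the blood, mesenchyme and neural crest, and surface ectoderm lists. Even a count of 0 could not pass there, so the rotation test of replicated peaks cannot decide on depletion of these lists. Hox genes, already at 0 of 39, had an unadjusted permutation p of 0.216. The ribosomal list passed with replicate 1 peaks alone (6 genes, adjusted permutation p 0.0460) and under 2 other backgrounds (range over 11 alternatives 0.0153 to 0.765), and the Hox and keratin lists passed against random genes of matched length (adjusted permutation p 0.0235 and 0.00977, ranges over 11 alternatives 0.0235 to 1 and 0.00977 to 0.877). On simulated peaks the test called 54.4% of planted enrichments in lists of under 80 members, so a small list not called can still be enriched. Depletion was not simulated, so how often the test would call it is unknown.

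In zinc finger genes the last exon, which encodes the finger array, carried a peak more often than the first. Of 387 zinc finger genes with at least 2 exons, 162 (41.9%) had a replicated peak on the last exon and 16 (4.13%) on the first. After rotation these shares were 6.15% (central 95% range 2.58 to 11.6) and 2.18%. The difference of 37.7 percentage points exceeded the rotated difference of 3.97 points (two-sided permutation p 0.002, the smallest possible). The first exon alone was not above rotation with replicated peaks (permutation p 0.182). It was above rotation with replicate 1 peaks (8.01%, rotated 3.80%, permutation p 0.0460) and with replicate 2 peaks (4.65%, rotated 1.54%, permutation p 0.0180). The same held with pooled peaks (10.1%, rotated 4.35%, permutation p 0.0180), but not in the other alternative settings. A smaller excess on first exons thus depends on the peak list. In the other 19974 protein-coding genes 3.58% of last exons carried a peak (rotated 3.40%; permutation p 0.466) and 2.28% of first exons (rotated 1.63%; permutation p 0.002). Last exons of zinc finger genes were longer, with a median of 2649 bp against 1261 bp in the other genes.

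**Figure D4:**
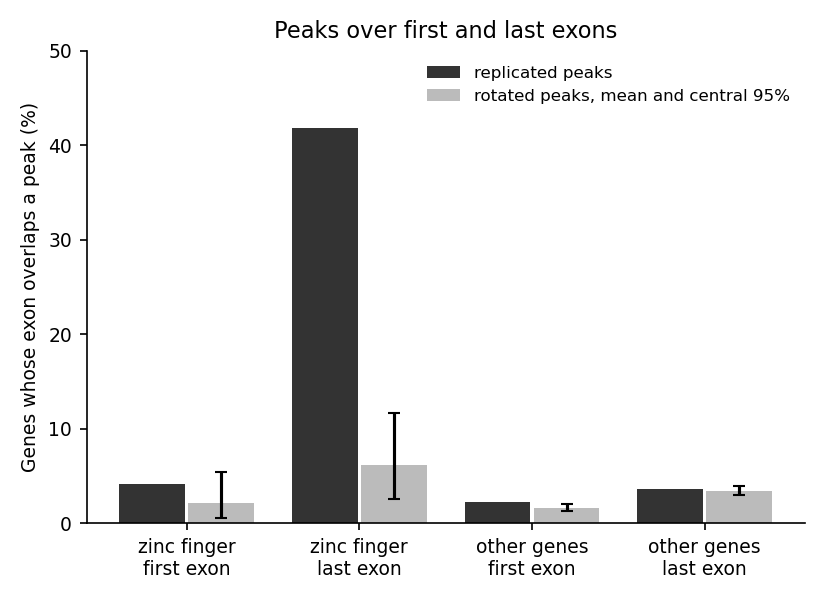
Percent of genes whose first or last exon overlaps a replicated peak (y axis), for 387 zinc finger genes and 19974 other protein-coding genes (black bars), with the mean over 1000 rotations (grey bars) and its central 95% range (lines). The last exon of zinc finger genes stands at 41.9%.

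Zinc finger genes in tandem clusters carried peaks more often than dispersed ones. A peak lay over 116 of 172 (67.4%) with at least 4 other zinc finger genes starting within 500 kb, and over 109 of 219 others (49.8%). The difference was 17.7 percentage points, against -1.65 on average after rotation (central 95% range -14.0 to 13.4; two-sided permutation p 0.012). With only the stronger 50% of the peaks by signal value it was 13.3 points (permutation p 0.0539, range over 9 alternatives 0.00400 to 0.0539).

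Several of the broadest domains of H3K9me3 held arrays of related genes, which was not tested for enrichment. Joined over gaps of up to 10 kb, the replicated peaks formed 18897 domains, of which 64.9% were single peaks. The 120 domains that spanned 100 kb or more held 31.6% of all covered bases, and 28 of them lay on chromosome 7. The 2 domains with most covered bases lay on chromosome 7, over genes of the carcinoembryonic antigen family (Ceacam5, Ceacam11 to Ceacam14; 17594595 to 18220516; 317 kb covered) and over secretoglobin genes including Scgb2b24 and Scgb2b27 (33388943 to 34074746; 314 kb). The next covered the protocadherin beta and gamma genes (chromosome 18, 37399036 to 37777750; 241 kb), the uncharacterised genes Gm12886 to Gm12888 (chromosome 4, 121258748 to 121736561; 221 kb), and a region of chromosome 12 with 0 protein-coding genes (114061951 to 114684422; 213 kb). Olfactory receptor genes from Olfr344 to Olfr362 lay in a domain on chromosome 2 (36552502 to 37151855; 205 kb), and the sulfotransferase genes Sult2a6 to Sult2a8 with the oocyte homeobox genes Obox7 and Obox8 in 1 on chromosome 7 (14186472 to 14674861; 178 kb). Vomeronasal receptor genes filled a domain on chromosome 5 (Vmn2r10 to Vmn2r17; 108949360 to 109571908; 177 kb) and another on chromosome 7 (Vmn2r51, Vmn2r52, Vmn1r66 and Vmn1r67; 10102141 to 10481299; 152 kb). The last of the broadest 10 joined olfactory receptor genes with Zfp616 on chromosome 11 (73832982 to 74218615; 143 kb). All 10 held peaks of both replicates. With peaks joined only over 5 kb, 8 of the broadest 20 overlapped the broadest 20 here. Such arrays of similar copies are regions where short reads can map to more than 1 place, and how the authors treated such reads was not given in the sources used here.

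Outside the gene lists, taking 1 gene per domain, the protein-coding genes with most covered bases were led by Gm42416, a read-through model that spans the protocadherin cluster (386920 bp), followed by Skint5 (111093 bp in 221 peaks; chromosome 4, 113477891 to 113999503) and Skint6 (83297 bp), genes of an immunoglobulin-like family of skin and thymus. Nlrp5 (39760 bp; chromosome 7, 23385889 to 23441922), a maternal-effect gene of the oocyte, and its relative Nlrp2 (35090 bp) were also covered. Mroh2a on chromosome 1 (88226986 to 88262289) was covered over 36448 bp by 4 peaks. Its covered bases were nearly equal in replicate 1 (36331 bp) and replicate 2 (35577 bp), unlike the other genes of this paragraph. No list of excluded regions was applied, and whether this is an artefact region was not examined. The remaining genes were the read-through model Gm20388 (35783 bp), A630089N07Rik (35181 bp), Gm4924 (33843 bp) and Gm20449 (27961 bp), which have no established function.

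Protein-coding genes as a whole were not favoured. A replicated peak overlapped 5424 of 21911 gene windows (24.8%), against 23.7% after rotation (two-sided permutation p 0.0939). By peak midpoint, 68.9% of peaks were intergenic, here meaning outside protein-coding genes and their promoters (rotated 59.4%, adjusted permutation p 0.004). In these genes 24.1% were intronic (rotated 33.8%, adjusted permutation p 0.004) and 3.53% exonic (rotated 2.81%, adjusted permutation p 0.00533). Within 1 kb of a transcript start lay 3.51% (rotated 4.03%, adjusted permutation p 0.0959). When any overlap with an exon counted in place of the midpoint, exons held 4.82% of peaks and were no longer above rotation (adjusted permutation p 0.498, range over 8 alternatives 0.00266 to 0.498). In 2 of these classes, introns and intergenic sequence, the unadjusted p was the smallest that the rotations can give.

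The bases under replicated peaks had a GC content of 45.2%, against 42.1% after 100 rotations (two-sided permutation p 0.0198, the smallest possible). Their observed over expected CpG frequency was 0.189 (rotated 0.193; permutation p 0.257) and 35.6% of them were repeat-masked (rotated 34.1%; permutation p 0.178). The CpG frequency differed from rotation in opposite directions in the replicates' own lists: it was 0.184 in replicate 1, below the rotated 0.192 (permutation p 0.0396), and 0.202 in replicate 2, above the rotated 0.193 (permutation p 0.0198, the smallest possible). Repeat-masked bases were above rotation with replicate 1 peaks alone (37.5%, rotated 34.4%; permutation p 0.0198) and with pooled peaks (36.3%, rotated 34.4%; permutation p 0.0198), and not with replicate 2 peaks alone (33.4%, rotated 34.1%; permutation p 0.277).

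Chromosome 7, which holds many of these gene arrays, had 32817 covered bases per Mb, the most of all chromosomes, followed by chromosomes 17 (19299), 4 (13678) and 13 (13176). Chromosome 1 had the fewest among autosomes (4675), and the median of the 19 autosomes was 8769. The X had 5560, 0.634 times that median, and within the range of the autosomes. The Y had 150. These values are per Mb of full chromosome length. Repeat-masked bases made up 96.3% of the Y and 46.8% of the X, against 36.4% of all chromosomes together. How much of each chromosome short reads can map was not examined, so the low Y value cannot be read as absence of the mark. The X value depended on the replicate: it was 1.02 times the autosome median in replicate 1 and 0.626 times in replicate 2. Replicate 1 had 10579 peaks on the X and replicate 2 had 2612, a ratio of 4.05, while the ratio on autosomes lay between 1.83 and 2.53 with a median of 2.14. On the Y the ratio was 6.86, from 240 and 35 peaks.

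**Figure D5:**
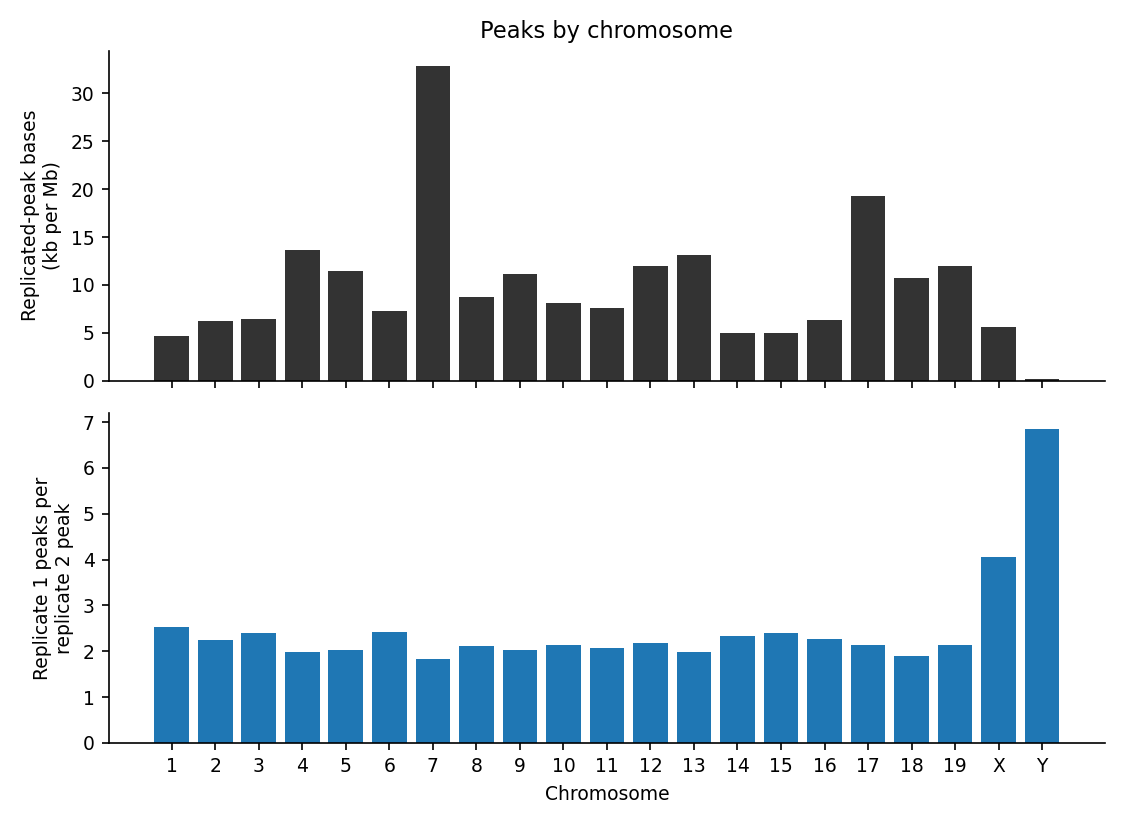
Replicated-peak bases per Mb of each chromosome (upper panel, y axis in kb per Mb) and the number of replicate 1 peaks per replicate 2 peak (lower panel), by chromosome (x axis). Chromosome 7 stands highest in the upper panel, and the X and Y, at 4.05 and 6.86, stand above the autosomes in the lower panel.

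The replicated list kept 28.7% of the pooled peaks, among them 96.5% of the decile with the highest signal values and 1.41% of the lowest decile. Kept peaks had a median width of 378 bp and the 131389 left out of 147 bp. Among the peaks left out, 48.2% overlapped a replicate 1 peak and 9.89% a replicate 2 peak. They too lay over zinc finger genes (287 of 391, 73.4%, against 46.8% after rotation; adjusted permutation p 0.0230) and near the starts of imprinted genes (17 of 28, against 26.7%; adjusted permutation p 0.0230), and the other 21 lists were not called with them.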

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

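For the values here, the test of the sex mix through the Y, and the peaks with −log10 q of at least 4, were chosen only after the results were seen, while the other tests of the X were set out before their results.

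Replicate 2 had 18 peaks on the mitochondrial genome, which has no histones, over 4833 bp and with a median signal value of 1.40. Replicate 1 and the replicated list had 0 there and the pooled list 4. These stand out as signal in sequence that no comparison used. The replicated list had 402 peaks on unplaced and unlocalized sequences, over 309 kb on 29 sequences with a median signal value of 4.79, which likewise entered no comparison.

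On the X replicate 1 had 4.05 peaks per replicate 2 peak, above every autosome (median 2.14) and below the Y. Base composition is argued against, since autosomal windows of 1 Mb drawn to the GC of the X windows gave a ratio of 2.19 (95% bootstrap interval 1.94 to 2.48). A larger share of females in replicate 1 than in its control could raise the X but would lower the Y. The Y ratio was 6.86 (95% interval 4.81 to 9.78), with 159 of the 240 replicate 1 peaks on the Y in its first 4 Mb. The Y ratio rests on 35 peaks in replicate 2 and was not taken at a stricter threshold. It therefore cannot exclude that the sex mix contributes to the X ratio. Weak peaks near the calling threshold stay open: with −log10 q of at least 2, the X ratio divided by the autosome median was 1.47 (95% interval 1.36 to 1.59), against 1.90 for all peaks, and with −log10 q of at least 4 the X ratio of 6.51 lay within the autosomes (3.29 to 7.12). The controls of the replicates differ and were not analysed here, and apart from the sex mix no biological explanation was tested, since the labels describe both pools alike.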

How the results depend on the processing

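For the dependence on processing, the rotation without runs of N, the peaks overlapping both replicates and the whole window of imprinted genes were chosen only after the results were seen. Of 384 alternative values for 45 results, 348 kept their call or moved by less than their limit. Another 10 lost their call, 10 gained one and 16 moved, and in 0 a call passed in the opposite direction. A change of direction without opposite calls was not counted separately. An example is the CpG frequency of replicate 2 peaks, which lay above rotation. Among 254 values for single gene lists 240 kept their call. Most of these belong to the 17 lists that were not called and stayed so, which says little about the calls. Of the called lists, the zinc finger call held in 10, the vomeronasal call in 9 and the cytochrome P450 call in 6 of 11 alternatives. The protocadherin, imprinted and germ cell lists passed in all 11 alternatives (adjusted permutation p at most 0.0460, 0.0153 and 0.0153). The share of zinc finger genes with a peak on the last exon exceeded that on the first by 32.8 to 44.4 points over 7 alternatives. No paired analysis was possible because there is only 1 group. With 2 replicates of unknown depth, a peak in 1 list alone cannot be separated from a difference in depth, and leaving out a replicate means using the other replicate's own list.

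With −log10 q of at least 2, replicate 1 kept 64112 peaks and replicate 2 22839; with the 50% of higher signal values, ties included, they kept 84074 and 32113, by construction. With peaks below either stricter threshold left out of both lists, 22.6% of replicate 1 peaks were shared. Over 6 alternatives the shared part of replicate 1 peaks ranged from 8.99 to 42.3% (26.0% as reported). That of replicate 2 peaks ranged from 19.6 to 75.4% (69.0% as reported), so it could also rise. The correlation of strength was 0.405 with 50% of both peaks overlapping and 0.312 on −log10 q. Exonic peaks were 4.82% by any overlap (adjusted permutation p 0.498).

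Leaving out replicates in turn gave 0 to 1 depleted lists, 138 to 167 vomeronasal genes, 40 to 55 cytochrome P450 genes, 5 to 6 ribosomal genes, an X density of 0.626 to 1.02 times the autosome median, 24170 to 41895 domains, a CpG frequency of 0.184 (replicate 1 peaks, below rotation) to 0.202 (replicate 2 peaks, above rotation) and 33.4 to 37.5% repeat-masked bases, above rotation with replicate 1 peaks alone. The pooled list, with more and weaker peaks, gave 177 vomeronasal genes (adjusted permutation p 0.230) and 57 cytochrome P450 genes (0.368), both no longer called, an X density of 0.969, 49483 domains and 36.3% repeat-masked bases (permutation p 0.0198). The cytochrome P450 call also ended with peaks overlapping both replicates (33 genes, rotated mean 16.99, adjusted permutation p 0.0842) and with the gene body alone (38 genes, rotated mean 20.6, 0.0613), at ratios to rotation near the 1.88 of the list as reported.

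Within 2 kb of the start 52 zinc finger genes carried a peak (adjusted permutation p 0.230). Rotation without runs of N gave 1 depleted list, the ribosomal list with 1 gene (adjusted permutation p 0.0197). Random genes matched on length, a background without the clustering of genes and peaks, gave 3 depleted lists, Hox with 0 genes (0.0235), keratin with 2 (0.00977) and ribosomal with 1 (0.0153), and called the olfactory list with 169 (adjusted permutation p 0.000657). The difference between clustered and dispersed zinc finger genes was 13.3 points with the stronger 50% of the peaks (permutation p 0.0539). At a merge distance of 5 kb 8 of the broadest 20 domains overlapped the broadest 20 at 10 kb. By −log10 q, 96.9% of the highest decile and 1.04% of the lowest decile of pooled peaks were kept. Except where stated, the cause was not tested.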

Other observations

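The name families, the test of long coding segments of any gene against zinc finger exons, and the genes named in this part were chosen only after results were seen; the window of 2 kb around gene starts was planned, and the other tests of zinc finger and coding exons were set out before their results.

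Germ cell and imprinted genes often carried peaks near the gene start. Within 2 kb of the start, 17 of 28 germ cell genes and 18 of 28 imprinted genes had a replicated peak (adjusted permutation p 0.0153 for each, range over 11 alternatives 0.000657 to 0.0153), against 52 of 391 zinc finger genes; the difference between the lists was not tested. All 9 imprinted genes without a peak near the annotated start had one elsewhere in the gene window, so that 28 of 28 had one there (rotated mean 8.35; two-sided permutation p 0.002, the smallest possible). In 6 of these the strongest peak covered an annotated promoter inside the gene: Grb10 (signal value 9.83; chromosome 11, 12025319 to 12028640), which encodes a growth-limiting adaptor, Plagl1 (9.82; chromosome 10, 13089875 to 13091876), Inpp5f (9.76; chromosome 7, 128687484 to 128688773), Impact (9.56; chromosome 18, 12971960 to 12974804), Mest (8.76; chromosome 6, 30735178 to 30740051) and Snrpn (7.24; chromosome 7, 60002887 to 60005207, the peak at the start of Snurf).

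Families of genes that share a name stem numbered 345, with at least 8 members each and 7383 genes in all. By the permutation (rotation) test with 20000 rotations, two-sided and adjusted over the families, 0 were called enriched and 0 depleted. An unadjusted permutation p below 0.05 was found for 6 enriched and 3 depleted families. For 345 families that is no more than the threshold would give with no association. The enriched ones included the Smad, Ube and Kbtbd families beside the families described next. Immunoglobulin variable genes, which are assembled only in lymphocytes, had a peak in 79 of 218 (36.2%, against 4.27% after rotation; permutation p 0.00360, adjusted 0.621), with 109 in replicate 1 and 70 in replicate 2. Heavy chain members such as Ighv9-4 and Ighv1-12 lie in the chromosome 12 domain at 114061951 to 114684422 that holds 0 protein-coding genes. Skint genes had a peak in 11 of 11 (rotated 45.0%; permutation p 0.0127, adjusted 0.730), with 11 in replicate 1 and 10 in replicate 2. Nlrp genes had one in 12 of 17 (rotated 36.4%; permutation p 0.0197, adjusted 0.971), with 14 in replicate 1 and 13 in replicate 2. Mitochondrial ribosomal protein genes of the large subunit had a replicated peak in 0 of 49 (rotated 12.4%; permutation p 0.00200, adjusted 0.621), but 9 had one in replicate 1 and 3 in replicate 2. Some families could not be called depleted at any count. Rassf genes, for example, had a peak in 0 of 10 at an unadjusted permutation p of 0.0819.

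The peaks over the last exons of zinc finger genes, found in 41.9% of these genes, are not explained by the properties tested. Reads shared between paralogs are argued against as the whole cause, since the 194 genes whose last exons have more unique 31-mers still had a peak in 33.0% (95% interval 26.4 to 40.1), although the other 193 had one in 50.8%. Length and base composition are argued against, since last exons of other genes drawn to the same length and GC classes had a peak in 5.15% (95% range 3.10 to 7.24). Coding segments of 2 kb or more outside the gene lists had a peak in 13.1% (95% interval 10.5 to 15.9), which argues against the length of coding sequence as the whole cause. A recruitment by the sequence of the finger array may remain as a hypothesis, which was not tested, and how the authors mapped repeated reads stays open.

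Long coding segments outside the gene lists nevertheless carried peaks more often than rotation gives. Of 635 coding segments of 2 kb or more, 83 had a replicated peak, 2.69 times the rotated number (two-sided permutation p 0.002, the smallest possible). Of untranslated segments of that length 2.42% had one, 0.483 times the rotated number (adjusted permutation p 0.00400). Overlapping coding segments, such as that shared by Akap2 and Pakap or those of Ank3, were counted separately. The set also held Gm42416, which spans the protocadherin cluster. Several zinc finger genes that the name pattern missed were in it too, among them Zfhx3, Zfhx4, Bcl11b, Sall4 and Zfp36l3. They were not removed, so the set is not free of zinc finger genes. The strongest peaks that overlapped such a segment were at Ccdc177, Shroom3, Peak1, Celsr1 and Plec, with signal values of 18.1, 13.5, 12.7, 12.4 and 11.8. At Peak1 peaks covered only 298 bp of the 3116 bp segment. Base composition stays open. Stretches of the same length and GC, free of coding sequence of genes outside the lists, had a peak in 5.40% (95% range 3.03 to 7.49). Of the 494 segments compared 12.1% had one, and the range reaches over the limit set for this explanation, 0.5 times that share. The stretches could still hold coding sequence of genes in the lists, such as zinc finger genes. A candidate explanation that the length of uninterrupted coding sequence itself goes with H3K9me3 thus cannot be told apart from base composition, and no biological explanation was tested.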
